A study of Mus musculus with 5 samples.

How the data were processed

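Cortices of wild-type mouse embryos at embryonic day 13.5 were dissociated and lysed with a mild detergent, and the supernatant of a slow spin was taken as the cytoplasmic fraction, per the labels' protocols. Part of it served as Input and part was precipitated on magnetic beads with an antibody against eIF4E or with rabbit control IgG. Libraries were made by Smart-seq2, which primes on poly(A) tails and amplifies full-length cDNA without marking strand or molecules. RNA without a poly(A) tail is therefore measured poorly, and amplification of small amounts can lose or inflate transcripts. Reads from overlapping genes on opposite strands cannot be told apart.

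The deposited table holds 1 column per library with abundances that are never negative, carry 2 decimals and are not on a log scale. The submitters' processing notes name STAR 2.7.9a, RSEM 1.3.3 and the build mm10. The header does not say whether the values are TPM or FPKM, which differ by 1 factor per library. Column totals were 718857 and 708778 (eIF4E), 838759 and 848550 (Input) and 560076 (IgG). Annotation version, options and any filter on rows are not given in the sources used here. Every value printed carries this limit: comparisons between genes within a library hold for either unit, whereas the level of a whole library against another depends on the factor. RSEM divides reads that match several genes among them, so values of genes with near-identical copies are uncertain. Depth is unknown from these values, so no counting intervals or floors are given.

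The table has 50161 rows, of which 286 repeat a gene ID with identical values and were dropped, leaving 49875 gene IDs, with symbols as the table pairs them. Coordinates were taken by symbol from a RefSeq gene table of GRCm38.p6, the assembly of mm10, which held 41 of the 51 genes named by the rule below outside the gene lists. Groups came from the sample titles: eIF4E (n = 2), Input (n = 2) and IgG (n = 1).

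Genes with a value of at least 1 in at least 2 of the 5 libraries were tested (12769). Values were transformed as log2(value + 1), so fold changes are on that scale and understate the change of low genes. limma 3.58.1 in R 4.3.3 was fitted to all 5 libraries with 3 groups (lmFit, eBayes with trend, two-sided, Benjamini-Hochberg adjustment over genes, threshold 0.05). The fit has 2 residual degrees of freedom, from the eIF4E and Input pairs, and 2.571 prior ones at the median. The lone IgG library is assumed to vary like the others, and comparisons with it have no replicate check of their own. The p-values measure the spread between these libraries.

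Before the data were examined, 40 gene lists (pathways, complexes, cell type markers), the tests and the rule for named genes were fixed. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one, and adjusted over the 40 lists. The estimated version rests on the 2 residual degrees of freedom and missed simulated lists of raised genes (below). A call lost with it therefore does not show that a list is unchanged. Counts within lists use the adjustment over all genes. Adjusted over the list alone they were the same in 30, 36 and 39 of the 40 lists in eIF4E against Input, eIF4E against IgG and IgG against Input, and differed by at most 2, 5 and 1 genes in the rest. The named genes are those past the threshold, with the libraries of both groups not overlapping, above the median abundance and without a predicted or clone name, ranked by absolute log2 fold change: 12 per direction for eIF4E against Input and 8 for each other comparison. In each list described, they are members among the 2 highest and 2 lowest log2 fold changes past the threshold. Eif4e, Eif4g1, Eif4ebp1, Eif4ebp2, Pabpc1, Eef1a1 and Malat1 are always named. Some genes that the rule picks are not reported here.

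Expected correlations and covariances came from 100 data sets of simulated unchanged groups, and expected overlaps from the product of the list sizes over the genes tested. The fit was tested on simulated data with 200 of 12769 genes changed by known folds. Every simulated library, IgG included, had the spread of the eIF4E and Input pairs, so the assumption about IgG was not tested. Far fewer genes changed than were called in the data, so the rates hold for that setting only. Genes were simulated as varying independently, so lists whose members vary together were not tested. For eIF4E against Input the fit recovered 4% of 1.25-fold, 12% of 1.5-fold, 46% of 2-fold and 88% of 4-fold changes, with 3 false calls among 78. For eIF4E against IgG it recovered 20% of 2-fold and 70% of 4-fold changes, with 1 false call among 54, and for IgG against Input 24% and 70%, with 1 among 50. A simulated list of raised genes was found at the preset correlation in every comparison, and at none with an estimated one (adjusted p = 0.113, 0.137 and 0.19).

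Alternatives covered the scaling between libraries (median of ratios, quantile, the same total for each library), filters on low values, pseudocounts of 0.1 and 10, limma without the trend, fewer libraries in the fit, a replicate block, each library left out, other thresholds and the estimated correlation. A correction for transcript length and GC content was planned and not run, since no transcript lengths or sequences were used here. Figures were drawn with matplotlib 3.10.9.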

Results

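The data were gene-level RNA abundances from an RNA immunoprecipitation experiment on wild-type mouse neocortex at E13.5, when progenitors of the cortical wall are producing neurons. In such an experiment an antibody against an RNA-binding protein is added to a lysate, and the RNA that comes down with the protein is sequenced. Here the protein was eIF4E, which binds the 5′ cap of mRNAs and starts the assembly of the translation initiation complex. There were 5 libraries: 2 from eIF4E immunoprecipitates, 2 from Input (the cytoplasmic supernatant that went into the precipitation) and 1 from a precipitate with control immunoglobulin G (IgG). The labels called the eIF4E and Input libraries biological replicates without saying which animals or pools they came from. The table gave RSEM abundances, either TPM or FPKM, and no counts, so the sequencing depth behind each value was unknown. Fold changes below are on the scale of value + 1.

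The replicate libraries lay close together. Across the 12769 genes tested, log2 abundances correlated with Pearson's r = 0.989 between both eIF4E libraries and 0.993 between both Input libraries (across genes, which are not independent replicates). A difference over 2-fold was found for 1.35% of genes in the former pair and 0.728% in the latter. The IgG library stood apart, with r = 0.596 and 0.593 to the Input libraries and 0.701 and 0.707 to the eIF4E libraries. It listed 11825 genes above 0, against 18677 and 18745 in eIF4E and 17529 and 17412 in Input. Of 5403 genes above 10 in each of the other 4 libraries, the IgG library listed 360 at exactly 0, where the other libraries listed at most 1. Values of 0 in IgG took part in the tests, rankings and counts as value + 1, and no fold against such a value is printed in this part. Mitochondrial 16S ribosomal RNA, mt-Rnr2, made up 5.22% of the IgG library, 0.113% and 0.11% of the Input libraries, and 0.00159% and 0.00156% of the eIF4E libraries.

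The mRNAs of the translation initiation machinery itself were followed first. Eif4e mRNA (chromosome 3, 138526191 to 138559696, GRCm38) measured 1265 ± 49.1 (SD, n = 2) in eIF4E, 201.4 ± 5.04 (SD, n = 2) in Input and 120.15 in the IgG library, a rise of 6.26-fold over Input (log2 2.65, SE 0.05, limma adjusted p = 4.8e-05) and 10.4-fold over IgG (adjusted p = 1.1e-05). Eif4g1, the scaffold that joins eIF4E to the ribosome, was 3.95-fold above Input and 2.66-fold above IgG. Pabpc1, the cytoplasmic poly(A)-binding protein, was 5.09-fold above Input and 1.76-fold above IgG. Eef1a1, an elongation factor with a terminal oligopyrimidine (TOP) leader, fell to 0.678 of Input, a direction that turned under quantile normalization, and did not pass the test against IgG (1.08-fold, adjusted p = 0.163), although it was lower than IgG after rescaling to the same total (log2 −0.23, adjusted p = 0.0358). Of the eIF4E-binding repressors, Eif4ebp1 fell to 0.504 of Input and 0.71 of IgG (adjusted p = 0.0089 against IgG). Eif4ebp2 fell to 0.463 of IgG (adjusted p = 4.5e-04). Against Input it did not pass (1.02-fold, adjusted p = 0.793), but was lower after median-of-ratios scaling (log2 −0.27, adjusted p = 0.0387).

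**Figure D1:**
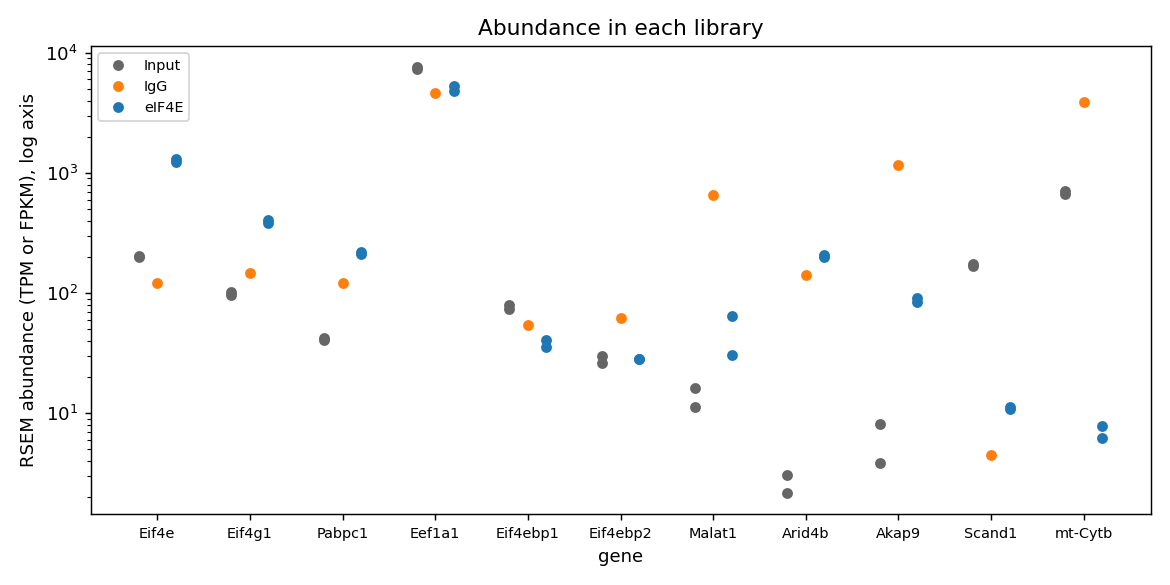
RSEM abundance (TPM or FPKM, log axis) of 11 named genes, with 1 point per library: Input (n = 2, grey), IgG (n = 1, orange) and eIF4E (n = 2, blue). Eif4e lies at 1230.61 and 1300.11 in the eIF4E libraries, above 120.15 in IgG and 197.83 and 204.96 in Input, whereas mt-Cytb lies at 6.17 and 7.88 in eIF4E, below every other library.

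The comparison of eIF4E with Input asks which cytoplasmic mRNAs were over- or under-represented with the cap-binding protein. With limma, 5535 of 12769 genes were higher and 3906 lower in eIF4E (adjusted p under 0.05), and 2970 and 927 of these differed by at least 2-fold. The largest rises among the more abundant genes were in Arid4b, a chromatin-associated protein, at 201.9 ± 5.86 (SD, n = 2) against 2.605 ± 0.629 (56.7-fold, log2 5.83, SE 0.13), Knl1, a kinetochore scaffold (log2 4.91), Atrx, a chromatin remodeller (23.3-fold), Pcm1 of the centriolar satellites (17.4-fold) and Dek (log2 4.00). They were followed by Kif5b, the kinesin-1 heavy chain, and Matr3, a nuclear matrix protein, at 15.2-fold each, Kif20b (log2 3.91), Sltm (14.7-fold), Ddx50 (14.5-fold), Hmmr (13.8-fold) and Akap9 (13.4-fold), each with an adjusted p of 5.1e-04 or less. Of these 12, Arid4b, Dek, Matr3, Ddx50 and Hmmr were also higher in eIF4E than in IgG, although quantile normalization took the difference for Arid4b to 0 and turned it for Matr3. Knl1, Atrx, Kif20b and Akap9 were lower in eIF4E than in IgG (Akap9 88.22 ± 4.80 against 1168.42), and Pcm1, Kif5b and Sltm did not pass against IgG.

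The genes that fell furthest below Input were mostly of mitochondrial origin. mt-Co3, mt-Atp6 and mt-Atp8 were listed at 0 in both eIF4E libraries and at means of 577, 436.2 and 298.7 in Input. mt-Nd1 fell to 0.00948 of Input (log2 −6.72, SE 0.19), and mt-Cytb, mt-Nd2, mt-Co1 and mt-Nd4 to between 0.0116 and 0.0237. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 fell to 0.012 and 0.013. The other genes among the 12 with the largest falls were Scand1, at 0.0699 of Input, and the histone gene H3c11, at 0.0911.

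As fixed lists, all 12 mitochondrially encoded mRNAs tested fell (5 of them listed at 0 in both eIF4E libraries; camera adjusted p = 2.4e-08). Of 69 listed replication-dependent histones, whose mRNAs end in a stem-loop, 14 were tested. The libraries were primed on poly(A) tails, so these values may not stand for the stem-loop mRNAs. Among the 14 tested, 13 were lower and none higher (14 lower adjusted over the list alone, camera adjusted p = 6.0e-05), from H1f2 at 0.682 of Input to H4c4 at 0.0804. The mRNAs of ribosomal proteins, which carry TOP leaders, also fell. Of those of the large subunit, 38 of 49 were lower and 3 higher (adjusted p = 8.0e-09), with Rplp0 at 1207 against 8170 (0.148), and with Rpl36al and Rpl5 at 1.97-fold and 1.65-fold. Of those of the small subunit, 28 of 33 were lower and 1 higher (29 lower adjusted over the list alone; adjusted p = 1.4e-08), with Rps12 at 0.178. The exception, Rps3a1 (1.10-fold), turned under median-of-ratios scaling. Ribosomal protein genes have many processed pseudogenes, so the value of a single member is uncertain. The list medians lay below the median of all genes by 1.41 (large) and 1.54 (small) on the log2 scale, and the histone median lay at −2.07. In the lone IgG library against Input these lists lay further below, at −2.05, −2.29 and −2.52 relative to all genes. The mitochondrially encoded mRNAs went the other way there, at 2.03. With an estimated inter-gene correlation the calls of these 4 lists were lost (adjusted p = 0.342 for the mitochondrial and histone lists and 0.572 for both ribosomal lists). That version also missed simulated lists of raised genes, so a loss with it, here and below, does not show that a list is unchanged. The simulated genes varied independently, so the simulation does not show that the preset holds for lists whose members vary together. The estimated correlations were −0.041 (mitochondrial), −0.026 (histones), 0.74 (large) and 0.65 (small), against the preset 0.01. If ribosomal members do vary together to that degree, their p-values at the preset are too small.

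Lists of energy metabolism and lysosomal content fell as well. Relative to all genes, the medians of glycolysis, respiratory chain, mitochondrial ribosome and lysosomal list lay at log2 −0.99, −0.78, −0.55 and −0.79. In the lone IgG library against Input they lay further below, at −1.32, −2.01, −1.37 and −1.11. Lower medians were thus not particular to eIF4E, as far as 1 IgG library shows. Glycolysis did not pass as a list there, and 11 of the 46 lysosomal genes were listed at 0 in IgG. Glycolysis had 13 of 18 genes lower, among them Gapdh (0.302) and Gpi1 (0.326), and 1 higher, Pdk1 (2.01-fold). The nuclear-encoded respiratory chain had 46 of 76 lower and 13 higher, and the mitochondrial ribosome 46 of 77 lower and 11 higher, Mrpl1 (4.56-fold) and Mrpl50 (4.20-fold) among the latter. Lysosomal hydrolases and membrane proteins had 33 of 46 lower and 5 higher. Naglu, which degrades heparan sulfate, stood at 0.174 of Input and Gaa, the acid glucosidase, at 0.334, whereas Pip4p2 and Asah1 were 1.84-fold and 1.62-fold higher. The camera adjusted p was 6.0e-05 for glycolysis, 2.5e-05 for the respiratory chain, 4.8e-05 for the mitochondrial ribosome and 3.2e-06 for the lysosomal list. With an estimated correlation all 4 calls were lost (adjusted p = 0.342 for glycolysis and the lysosomal list, 0.572 for the others), and the respiratory chain's was also lost under quantile normalization (adjusted p = 0.134).

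Markers of some non-neural cells fell too: 11 of 13 erythroid genes (Hbb-bh1 at 0.224 of Input), 13 of 21 endothelial and mural genes (Vtn at 0.344 and Slc2a1 at 0.363) and 9 of 15 microglial and immune genes (C1qc at 0.336), with 2, 2 and 1 higher. Their camera adjusted p was 0.00151, 0.00151 and 0.0161, and with an estimated correlation 0.572, 0.405 and 0.572. The estimated correlations were 0.8, −0.039 and 0.24, against the preset 0.01. Relative to all genes their medians lay at log2 −1.50, −0.87 and −0.91. In the lone IgG library against Input they lay further below, at −2.17, −1.55 and −1.70, with 2, 11 and 11 members listed at 0 in IgG. The erythroid markers did not pass as a list there. The microglial call was lost without eIF4E replicate 2 (adjusted p = 0.0574). Markers of meninges and mesenchyme did not pass as a list (9 of 15 lower and 4 higher, with Dcn at 2.55-fold and Lum at 2.38-fold; camera adjusted p = 0.0756), but passed without Input replicate 2 (adjusted p = 0.0467), after rescaling to the same total (0.0302) and among genes above 0 in all 5 libraries (0.0218).

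As lists, 4 rose. Chromatin regulators had 28 of 36 genes higher and 3 lower (camera adjusted p = 1.7e-04), with the corepressor Ncor1 at 8.57-fold and the methyltransferase-family gene Kmt2e at 8.52-fold. RNA-binding proteins of neurons and progenitors had 29 of 36 higher and 6 lower (adjusted p = 0.00126), with Pum2 at 5.75-fold and Fxr1 at 5.11-fold, and with Ptbp1 at 0.455 and Msi1 at 0.518. Markers of newborn and cortical neurons had 23 of 35 higher (24 adjusted over the list alone) and 5 lower (adjusted p = 0.0177), with the transcription factors Myt1l at 6.97-fold and Sox11 at 6.07-fold and the tubulin Tubb3 at 0.611. Axon guidance and adhesion receptors had 28 of 40 higher and 8 lower (adjusted p = 0.0197), from the ephrin receptor Epha3 at 7.56-fold to the ligand Efnb1 at 0.323. With an estimated correlation the adjusted p of these lists was 0.342, 0.564, 0.439 and 0.439. The axon guidance call was also lost among genes above 0 in all 5 libraries (adjusted p = 0.0595). In the same order, these list medians lay at log2 1.09, 0.83, 0.50 and 0.87 relative to all genes. In the lone IgG library against Input they lay higher, at 2.46, 1.62, 1.51 and 2.47. Against IgG the RNA-binding list had a median of −0.12. Of the risers named here only Pum2 was lower in IgG (52.16) than in eIF4E (58.3), and Kmt2e measured 379.11 against 153.6.

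The remaining lists did not pass as groups, although many of their members did. Besides meninges, 4 of them passed under some alternatives: mitosis and G2/M higher (quantile normalization, camera adjusted p = 1.7e-04, and the same total, 0.038), long noncoding RNAs higher (no filter, 0.0202), proteasome subunits lower (median-of-ratios scaling, 0.046, and without eIF4E replicate 1, 0.0222) and oligodendrocyte precursors and choroid plexus lower (no filter, 0.0117, and the same total, 0.0376). The cap-binding complex and its regulators had 8 of 15 higher and 2 lower, with Eif4g3 at 11.8-fold (camera adjusted p = 0.232). Translation factors with TOP mRNAs went both ways, 8 of 22 higher and 12 lower (9 and 13 adjusted over the list alone), with Eif3a at 9.58-fold and Eif4a2 at 6.34-fold, and with Eif3f at 0.175 and Eef1g at 0.231. The mTORC1 and nutrient-sensing list had 15 of 34 higher and 11 lower, from the S6 kinase gene Rps6kb1 (5.20-fold) to Akt1s1 (0.403). Lysosome positioning genes had 10 of 24 higher and 9 lower, V-ATPase subunits 6 of 18 higher and 8 lower, and autophagy genes 10 of 25 higher and 9 lower. Radial glia markers had 14 of 28 higher and 10 lower, with Fabp7 at 3.82-fold and the Notch effector Hes1 at 0.267. Intermediate progenitor markers had 12 of 19 higher (13 adjusted over the list alone) and 5 lower, with the RNA-binding protein gene Elavl2 at 6.53-fold. Of the mRNAs described elsewhere as eIF4E-sensitive, 9 of 22 were higher, Nbn (7.16-fold) and Hif1a (5.04-fold) among them, and 6 were lower, Fth1 (0.294) and Ccnd3 (0.491) among them. Among the risers named in this paragraph, Eif3a, Eif4a2, Elavl2 and Hif1a had higher values in IgG than in eIF4E. Eif4g3, Rps6kb1, Fabp7 and Nbn had lower ones.

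**Figure D2:**
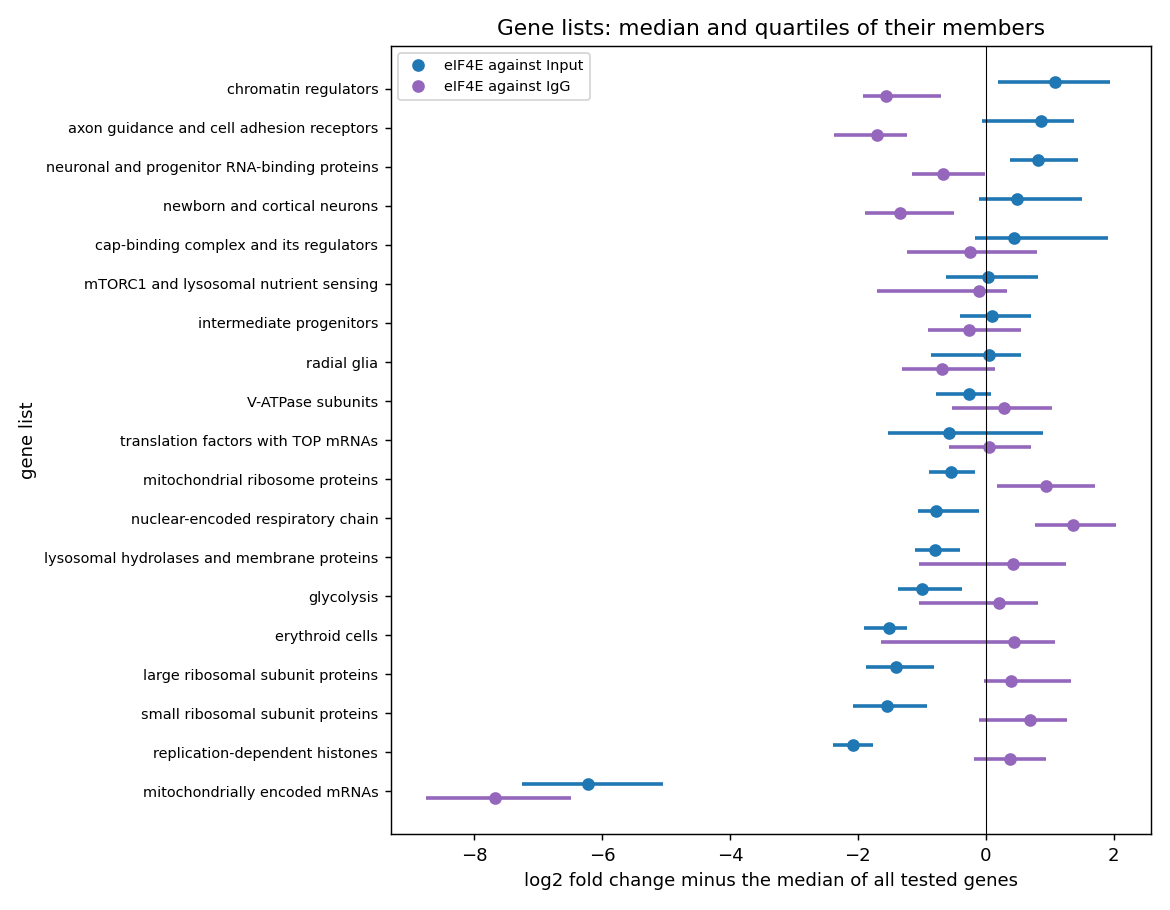
Median (point) and quartiles (line) of the members' log2 fold changes, minus the median of all tested genes, for 19 of the 40 gene lists, in eIF4E against Input (blue) and eIF4E against IgG (purple). Ribosomal protein lists lie at −1.41 and −1.54 against Input and at 0.40 and 0.70 against IgG, and chromatin regulators at 1.09 and −1.57.

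The comparison of eIF4E with IgG asks which mRNAs had a higher or lower relative abundance than in the control precipitate. The amount of RNA in each precipitate is not known from these values. Higher or lower therefore does not mean above or below background in amount. The same holds for the genes higher than both controls, given below. With 1 IgG library, assumed to vary like the other groups, 6785 genes were higher and 3912 lower in eIF4E. The largest rises by the fixed rule were in genes listed at 0 in IgG, among them Edf1 (418.8 ± 37.2, SD, n = 2, in eIF4E), Med21 (142.6), Arxes2 (117.9), Nudt2 (113.5), Mrpl43 and Mcfd2 (112.6 each) and Thyn1 (108.8). Restricted to genes above 0 in all 5 libraries, 4326 were higher and 3870 lower. All 8 of the largest falls within the naming rule, which leaves out genes of low mean log2 value, were mitochondrial, with mt-Rnr2 (11.23 against 29258.14) and mt-Cytb (7.025 against 3901.36) first. Outside it, mt-Atp6 (log2 −10.42) and mt-Co3 (log2 −9.39), listed at 0 in eIF4E, fell further than mt-Cytb on the scale of value + 1. The size of a fall to 0 depends on the pseudocount, so this order does too. The rule also left out the nuclear gene Nrxn3, at 1.32 in eIF4E against 228.62 in IgG. Its fall of log2 −6.63 exceeded that of mt-Nd2 (log2 −6.07), which the rule picked. Of the mitochondrially encoded mRNAs 11 of 12 were lower (camera adjusted p = 4.9e-07, and adjusted p = 0.444 with an estimated correlation).

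Against IgG the mRNAs of nuclear-encoded mitochondrial proteins rose: 71 of 76 respiratory chain genes were higher and 2 lower (Ndufc1 at 41.5-fold and Cox6b1 at 31.5-fold; camera adjusted p = 7.6e-07), as were 61 of 77 mitochondrial ribosome genes, with 8 lower (adjusted p = 2.6e-04). Proteasome subunits had 26 of 31 higher and 1 lower (adjusted p = 0.00471). Ribosomal protein lists had 38 of 49 and 28 of 33 members higher (adjusted p = 0.0378 for each), Rpl35a at 11.5-fold and Rps28 at 12.7-fold among them. Both ribosomal calls were lost without either Input replicate (adjusted p = 0.0609 and 0.0604) and under several other alternatives. The lists that fell were axon guidance and adhesion receptors (32 of 40 lower, with Dcc, the netrin receptor, at 0.068; adjusted p = 4.0e-07), chromatin regulators (24 of 36 lower; 4.3e-05), newborn and cortical neurons (22 of 35 lower; 9.4e-04) and nuclear-retained and long noncoding RNAs (7 of 10 lower, 8 adjusted over the list alone, with Meg3 at 0.0489; 0.0074). The noncoding RNA call was lost with a filter of at least 5 in 2 libraries (adjusted p = 0.0862). None of the 10 list calls held with an estimated correlation (adjusted p = 0.444 to 0.788).

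The comparison of IgG with Input shows what the control precipitate held. In it 4823 genes were higher and 6428 lower, a balance that turned after rescaling each library to the same total (5827 and 5460) and among genes above 0 in all 5 libraries (4787 and 4034). The latter restriction leaves out genes listed at 0 in IgG, which cannot be higher there, so it shifts the balance by construction. The largest rises by the fixed rule were in Akap9 (175-fold), Atrx (111-fold), Cenpe (108-fold), Nrxn3 (93.6-fold), Macf1 (75.8-fold), Kif20b (69.1-fold), Thoc2 (64.6-fold) and Blm (64.0-fold). Malat1, a nuclear noncoding RNA, measured 651.78 in IgG, 13.75 ± 3.52 (SD, n = 2) in Input and 47.32 ± 23.9 in eIF4E. The 8 largest falls (Edf1, mt-Atp8, Tbcc, Coro1a, Hba-a2, Mrpl43, Commd5 and Hmces) were genes listed at 0 in IgG. All 10 nuclear-retained and long noncoding RNAs were higher (camera adjusted p = 6.4e-04), as were 31 of 36 chromatin regulators and 32 of 40 axon guidance receptors (2.2e-06 for each), whereas 71 of 76 respiratory chain genes, 44 of 49 large and 32 of 33 small ribosomal subunit genes were lower (6.6e-08, 9.7e-06 and 2.6e-05). With an estimated correlation the adjusted p of the 15 lists past the threshold was 0.498 to 0.582.

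**Figure D3:**
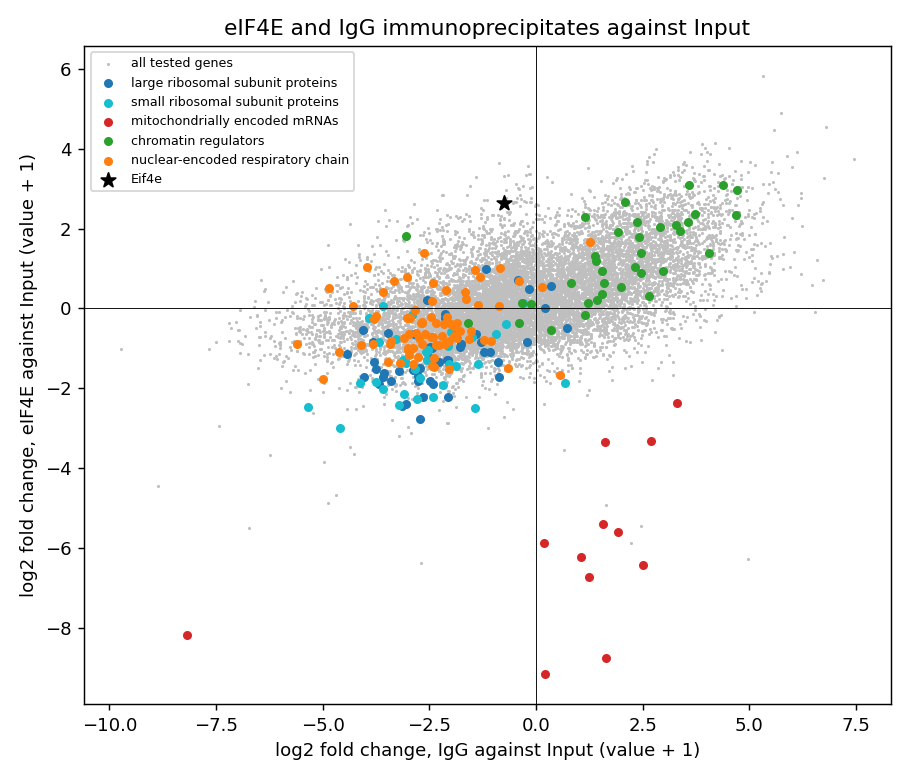
Each point is a tested gene, with its log2 fold change (value + 1) in IgG against Input on the x axis and in eIF4E against Input on the y axis, and 5 gene lists and Eif4e in colour or as a star. Across the 12769 genes both axes correlate with r = 0.56, Eif4e lies at −0.74 and 2.65, and the mitochondrially encoded mRNAs lie lowest on the y axis.

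Both precipitates differed from Input in the same direction for many genes. Of the 5535 genes higher in eIF4E, 3419 (61.8%) were also higher in IgG, where independent lists of these sizes would share 2091, and of the 3906 lower, 3058 (78.3%) were also lower, where independent lists would share 1966. Log2 fold changes correlated with r = 0.56 across genes, and simulated unchanged groups gave 0.41. The covariance was 1.31 against a simulated 0.0123, a difference of 1.30. With a different Input library in each comparison, a split chosen after seeing the data, r was 0.55 and the covariance 1.29 in either arrangement.

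By both controls together, 2530 genes (19.8%) were higher in eIF4E than in Input and in IgG, against 2941 for independent lists of these sizes. Both sets of log2 fold changes, which share the eIF4E libraries, correlated with r = −0.09 (simulated 0.41), with a covariance of −0.175 (simulated 0.0123). Of these, 780 were listed at 0 in IgG and 1750 were above 0. By a rule of size without a test, 693 genes were at least 2-fold higher in every eIF4E library than in every Input and IgG library, 299 of them listed at 0 in IgG. Scaling moved both counts, to 1572 (quantile normalization) from 2530 and to 461 (median of ratios) and 346 (quantile normalization) from 693, and the latter was 393 among genes above 0 in all 5 libraries and 154 with a pseudocount of 10. No fixed list was enriched or depleted among the 2530 genes after adjustment (Fisher's exact test, two-sided, over 40 lists). The smallest adjusted p was 0.274, for the ribosomal protein lists, with 3 of 49 and 1 of 33 members among them, and the proportion was 11 of 30 for DNA replication genes (adjusted p = 0.28).

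The division of calls between higher and lower depended on the scaling between libraries. In eIF4E against Input 58.6% of calls were higher with the values as deposited, 46.2% after median-of-ratios scaling, 45.5% after quantile normalization and 70.4% after rescaling each library to the same total. The median log2 fold change of all genes was 0.16, −0.10, −0.11 and 0.38 in the same order. In eIF4E against IgG 63.4% of calls were higher as deposited and 48.8% after quantile normalization, with medians of 0.55 and −0.04. In IgG against Input 42.9% were higher as deposited, 39.7% after median-of-ratios scaling, 49.4% after quantile normalization and 51.6% after rescaling to the same total, with medians of −0.43, −0.57, −0.06 and 0.04. Among genes above 0 in all 5 libraries it was 54.3%.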

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

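Rescaling each library to the same total, the restriction to genes above 0 in all 5 libraries and the pseudocount of 10 were chosen after seeing the data. By construction, the restriction leaves out genes listed at 0 in IgG, which cannot be higher there. The cause was not tested unless an alternative's construction shows it. No list changed direction with a call on either side, and among named genes 18 values did.

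The count of genes at least 2-fold higher in every eIF4E library (693) became 461 after median-of-ratios scaling, 346 after quantile normalization, 393 among genes above 0 in all 5 libraries and 154 with a pseudocount of 10. By construction it was 1447 at 1.5-fold and 215 at 3-fold. Genes higher than in both controls (2530) became 1572 after quantile normalization. Requiring a 2-fold change left 873 of them, and 2970 higher and 927 lower than Input and 2428 lower than IgG. Among genes above 0 in all 5 libraries, with fewer genes tested, 4326 were higher than IgG and 4034 lower in IgG than in Input. With an estimated correlation the lists past the threshold fell to 0 in each of the 3 comparisons, from 15, 10 and 15 (5, 4 and 3 at an unadjusted p under 0.05). Under the other alternatives, 5, 5 and 7 further lists passed in at least 1 of them and none in all, and 3, 3 and 4 lists lost their call in at least 1.

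Log2 fold changes turned after median-of-ratios scaling for Thyn1 (−0.11), Eif4ebp2 (−0.27) and Rps3a1 (−0.17) against Input. After quantile normalization they turned for Eef1a1 (0.44), Rps6 (0.05), Emcn (−0.08), Lyz2 (−0.15) and Pgk1 (0.02) against Input, for Arid4b (0), Matr3 (−0.41), Wnt3a (−0.55), Folr1 (−0.57) and Psmc1 (−0.5) against IgG (Wnt3a and Folr1 listed at 0 there), and for Eef1a1 in IgG against Input (0.32). After rescaling to the same total they turned for Matr3 (−0.04), Eef1a1 (−0.23) and Psmc1 (−0.16) against IgG and for Eif4ebp1 in IgG against Input (0.09).

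Leaving out each library gave 4817 to 5542 genes higher and 2935 to 3907 lower than Input. With the replicate block 5401 were higher and 3749 lower and 15 lists passed. The numbers pair nothing known: deviations of same-numbered libraries correlated at 0.02 over all genes (−0.14 in the more abundant part), and the labels name no shared lysate. Unknown depth and the lone IgG library limit every comparison with IgG. The count-based filters, scaling and tests meant for tables of counts were not run, since the values are not counts, and neither was the correction for transcript length and GC content, since no transcript lengths or sequences were used here.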

Other observations

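All tests in this part were chosen after the results they bear on had been seen.

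Among the genes higher in eIF4E than in both controls, above 0 in IgG and above the median of the mean log2 value, those with the largest smaller-of-both change were, by a rule set after the data were seen, Cenpq, a centromere protein (10.3-fold over Input), Usp1 (8.19-fold), Cep57 (7.16-fold), Tfb2m (6.82-fold), Eif4e itself and Nae1 (5.13-fold). Ran, the GTPase of nuclear transport, was the most abundant of the leading 20, at 3619.62 and 3103.76 in eIF4E, 596.58 and 777.52 in Input and 86.59 in IgG.

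Genes higher in eIF4E than in Input were often higher in IgG as well (3419 genes). Chance values of the shared Input libraries gave a simulated covariance of 0.0123, against 1.31 observed. RNA of the kind in the IgG library carried into the eIF4E libraries would bring its mitochondrial mRNAs along. The genes higher in both precipitates would need 33.5% of the IgG level at the median (lower quartile 17.9%). The 11 mitochondrially encoded mRNAs above 10 in IgG reached at most 1.59% of it (mt-Nd5). This argues against a background of that IgG library's composition, though not of another one. It rests on 1 IgG library, so whether that composition recurs is unknown. Loss of short mRNAs from both kinds of precipitate stays open: 5 of 5 lists of mostly short mRNAs lay below the median of all genes in both, but no transcript lengths were used here, and an affinity of eIF4E for these mRNAs was not tested apart from it.

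Mitochondrially encoded mRNAs were far lower in eIF4E than in Input and IgG, and a scaling factor per library, which moves all genes alike, is excluded by the list lying at −6.21 relative to all genes. Loss of mitochondria before the precipitation would lower Input too, which per the labels' protocols comes from the same supernatant, and which held at least 0.498% mitochondrial mRNA, against 0.00641% and 0.00654% in eIF4E. That test replaced an earlier one on the share in the IgG library (2.3%), which had left this loss undecided because it rested on 1 library. In the lone IgG library the same mRNAs lay above Input, at a median of 3.03-fold, although mt-Atp8 was listed at 0. For the fall against Input, a candidate explanation is that RNA without a cap is not held by eIF4E. RNA enclosed in mitochondria out of reach of the antibody is another. Neither says why the control precipitate held mitochondrial RNA that the eIF4E precipitates hardly held, and this was not tested. RNA polymerase III transcripts, also without the cap that eIF4E binds, were to separate these candidates, but 0 of 6 looked for passed the filter. Libraries primed on poly(A) tails measure RNA without a tail poorly, so this test could not decide, and both stay open.

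Eif4e mRNA rose with its own protein. Reads shared with its paralogs do not account for it: Eif4e3 changed by 0.75 on the log2 scale and Eif4e2 by 0.01 against Input. Few mRNAs shared a rise of that size: 19 of the 12769 genes rose at least as far against both controls (0.15%), 9 of them above 0 in IgG. The IgG values of these 9 ran from 0.04 (Nbn) to 3.89 (Cenpq), against 120.15 for Eif4e, so their folds over IgG rest on low values. The share of 0.15% lay between the limits for and against a shared rise, which were set after the data were seen, so that explanation is not excluded. Capture of the nascent eIF4E protein on its own ribosomes by the antibody may be a further cause, and nothing measured here bears on it.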
